A study of Mus musculus with 65 samples.

How the data were processed

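Single hematopoietic stem cells were sorted from the bone marrow of aged mice, older than 20 months per the labels, that carried an SCL-driven tetracycline transactivator and a histone H2B-GFP reporter. In such mice the GFP label is made until it is switched off and is then thinned out by each division, so a cell that stays GFP positive has divided rarely since. The sorted cells were long-term stem cells by surface phenotype (lineage depleted, Sca-1 and Kit positive, CD34 negative or low, Flk2 negative, CD48 negative, CD150 positive). GFP-positive cells are called label-retaining here and GFP-negative cells non-label-retaining. Per the labels' protocols the cells spent a night in culture without growth factors at 3% oxygen, cDNA was made with the SMART-Seq v4 kit, which amplifies full-length polyadenylated RNA and marks neither strand nor molecule, and Nextera XT libraries were made by hand. The series holds 65 cells, 37 label-retaining and 28 non-label-retaining, from 4 biological repeats per the series design. Repeats 1 to 4 gave 9, 9, 10 and 9 label-retaining and 8, 4, 6 and 10 non-label-retaining cells.

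As deposited, the values are estimated counts per gene and cell that the authors made from reads on the mm10 build before deposit, and the authors name DESeq and call the table normalized. The aligner, the counter and the annotation are not given in the sources used here. The values themselves show no scaling: the sum per cell runs from 86 to 20516069, and among values between 0.5 and 20 a median of 74.7% per cell (range 59.5 to 100.0%) are whole within 0.0001. The others are fractions, as when a read that maps to several genes is shared out. The deposited values were therefore treated as estimated (expected) counts that are not normalized, and rounded to whole numbers after summing. The table was keyed by NCBI gene identifiers, which were matched to symbols and mm10 coordinates through RefSeq for GRCm38.p6. Of 18036 identifiers 16262 matched, and the 1774 others took 0.11% of all counts. The table covers 46.9% of the 21900 protein-coding genes of that annotation. It holds no gene of 5 chromosomes (3, 4, 15, 16 and the mitochondrial genome), 1 of chromosome 2, and a minority of those of chromosomes 5, 8, 9, 14, 17, 19, X and Y. Totals per cell are therefore totals over this part of the genome and not full library depth, and shares of counts are shares of this part. Notch1, Cdc42, Cdkn1a, Cdkn2a, Procr, Cd34, Kit and Mecom are not analysed here.

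Groups, tests, gene lists, the rule for named genes and most alternatives were set before the data were examined. Cells are not replicates, so the repeat was the unit and each comparison set 4 values against 4. The planned gene test, limma on log2 means of normalized values, assumed scaled values. Because the values proved to be unscaled, counts were summed over the cells of each repeat and group and tested with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3, TMM factors, robust fit, Benjamini-Hochberg adjustment, threshold 0.05). Genes with a mean over the 8 means per cell of at least 10 and a count in at least 10 cells were tested, 2786 of the 6826 with any count. In each table of levels, CPM is the sum of a gene relative to the TMM-scaled total of the tested genes, computed here. The TMM factors were 0.29 and 0.22 for non-label-retaining repeats 3 and 4 and 1.44 to 2.04 for the other sums. This scaling raises every CPM of those repeats relative to the other sums. On simulated counts with the estimated spread (common dispersion 3.42, 2786 genes, 200 of them changed) the test called 0% of the 4-fold, 16-fold and 64-fold changes of this comparison, with the right direction in 76.1%, 91% and 98.5%, and called 0 of 2586 unchanged genes. With a dispersion of 0.1 it called 100% of all 3 sizes and 9 of 2586 unchanged genes. A count of 0 genes from it therefore does not show that the groups are alike.

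Gene lists were tested with camera (limma 3.58.1, preset correlation 0.01, at least 5 tested members), with an estimated correlation and fry beside it. The 26 fixed lists were HSC identity, quiescence and dormancy, S phase, G2 and M phase, genes higher in aged HSC, megakaryocyte and platelet, lymphoid priming, myeloid priming, Notch pathway, Cdc42 and polarity, niche adhesion and cytokine receptors, interferon response, inflammation and NF-kB, immediate early genes, heat shock and chaperones, unfolded protein response, p53 and DNA damage, apoptosis, autophagy and lysosome, glycolysis, hypoxia response, oxidative phosphorylation, cytosolic ribosomal proteins, the mitochondrial genome, ribosome biogenesis and Myc targets, and epigenetic regulators. Of these, 21 had enough tested members. The 10 marker lists of other cell types were erythroid, neutrophil, monocyte and macrophage, B cell, T and NK cell, mast cell and basophil, dendritic cell, megakaryocyte progenitor, endothelial and mesenchymal stroma, and 0 of them had 5 tested members. Named genes were the 10 of each direction with the smallest unadjusted p among those with the same sign in all 4 repeats (since fewer than 10 passed the threshold), the up to 3 members of each list with the smallest p, and 19 genes fixed by name, of which 11 are in the table. Genes per cell, similarity between cells and the share of cells with cycling transcripts were compared with two-sided exact permutation tests of the 4 against 4 means per repeat (70 assignments, smallest possible p 0.0286). A sign-flip test of the 4 paired differences cannot go below 0.125. Shares over cells have exact binomial 95% intervals, which cover counting error only, since reads without molecular identifiers are not independent molecules.

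Tests of the share of cells in which a gene, or the members of a list, were detected (a count above 0) were added after the data were examined. They compare the mean share per repeat by the same exact permutation test. The share of a list is over its members with a count in any cell, for HSC identity 11 of 33. For a comparison at like depth, the rounded counts of each cell were thinned to 10000, which leaves out the 4 cells under 10000 counts, all non-label-retaining. Computations outside R used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. Figures were drawn with matplotlib 3.10.9.

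Repeat numbers come from the labels and are shared by both groups. Sums with the same number deviated together from their group means (correlations 0.56, 0.27, 0.17 and 0.15 over genes for repeats 1 to 4), while unlike numbers lay between -0.32 and 0.16, the highest for label-retaining repeat 4 with non-label-retaining repeat 3. Without the 2 cells of repeat 1 that share a profile the values were 0.29, 0.25, 0.15 and 0.11. By the rule set beforehand, a correlation over 0.1 in every pair, the numbers pair the samples, weakly in repeats 3 and 4, and the fit with the repeat as a block is given where it changes a call. For shares of cells or members the paired test is the sign flip, which ends every call at 0.0286. All libraries carry the same run and lane label, and index positions within it place the cells of a repeat and group side by side. The most similar cells, label-retaining cells 20 and 21 of repeat 3 (r = 0.973), are separate cells in the labels and were kept as such. Their difference beyond counting error (chi-square per degree of freedom 22.3) does not settle this, since amplified reads of the same cDNA would also exceed it. Alternatives covered DESeq2 1.42.0, other scalings and filters, limma on rescaled values, left-out cells, left-out repeats and thinned counts.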

Results

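The series asked how aged hematopoietic stem cells that have kept a histone label, and so have divided rarely, differ from those that have lost it. The title places the label-retaining cells in perisinusoidal niches of the marrow. The measurement was RNA-seq of 65 single long-term stem cells from mice older than 20 months, 37 label-retaining and 28 non-label-retaining, in 4 biological repeats. Total counts over the part of the genome analysed here ran from 27954 to 20516069 per label-retaining cell (median 264894) and from 86 to 661078 per non-label-retaining cell (median 118056). By repeat the medians were 1654517, 697583, 201268 and 164961 in label-retaining cells and 65358, 41004, 271753 and 201757 in non-label-retaining cells, so median depth favoured the label-retaining cells in repeats 1 and 2 and not in repeats 3 and 4. The deepest cell held 60.8% of the summed counts of label-retaining repeat 1.

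Label-retaining cells had transcripts of more genes. They showed 1924 ± 446 genes per cell and non-label-retaining cells 1090 ± 277 (mean ± SD over repeats, n = 4 each), a difference of 834 that held in 4 of 4 repeats (exact permutation p = 0.0286, the smallest possible). Counting only genes with 10 or more counts, the means were 975.6 ± 288 and 307.4 ± 104 (exact permutation p = 0.0286). After thinning every cell to 10000 counts the means were 864.7 ± 240 and 572.4 ± 309, higher in label-retaining cells in 3 of 4 repeats (exact permutation p = 0.229). In repeats 3 and 4, where non-label-retaining cells were sequenced at least as deeply by the median, thinned cells showed 825 ± 89.4 against 305 ± 40.4 genes, and in repeats 1 and 2 904 ± 398 against 840 ± 16.3 (n = 2 repeats each). The pairing of the repeats gave p = 0.125 by exact sign flips, the smallest they can give. Without the 4 non-label-retaining cells under 10000 counts the difference was 682.8 (exact permutation p = 0.0571), and repeat 2 then lay the other way.

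**Figure D1:**
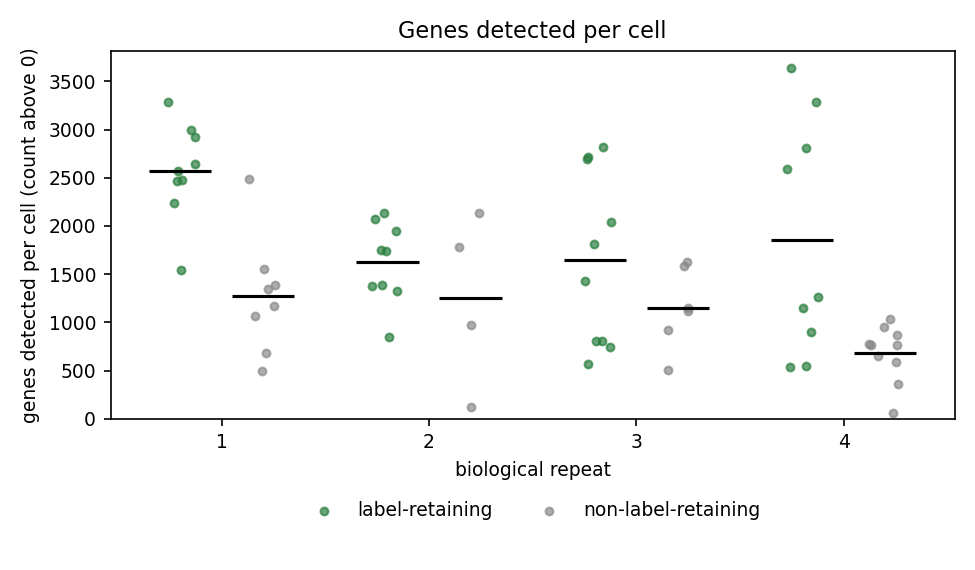
Genes with a count above 0 in each cell (vertical axis) by biological repeat (horizontal axis). Green points are label-retaining cells, grey points non-label-retaining cells, black lines the mean of each repeat and group. The mean of label-retaining cells lies above that of non-label-retaining cells in all 4 repeats, by 834 genes on average.

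Genes seen in label-retaining cells and in almost none of the others led the comparison of single genes. Kidins220, a scaffold of receptor signalling at the membrane, was detected in 19 of 37 label-retaining and 0 of 28 non-label-retaining cells. Nfe2l1, a transcription factor of proteasome genes, was detected in 15 and 0, Stat6, the transcription factor of interleukin-4 signalling, in 18 and 0, the PHD finger gene Phf23 in 17 and 0, and the dynactin subunit Dctn4 in 17 and 0. The Y-linked gene Uty was found in 12 and 0 cells (other Y-linked genes were likewise scarce in non-label-retaining cells), the RNA helicase Dhx30 in 17 and 1, the sphingosine-1-phosphate lyase Sgpl1 in 15 and 1, the F-box gene Fbxo33 in 10 and 1, and the schlafen pseudogene Slfn10-ps, whose reads can be shared with its family, in 14 and 2. A count of 0 in 28 cells allows a share of cells with a read of up to 12.3% (exact 95% limit), which limits detection in libraries of this depth and not expression.

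None of these genes passed the threshold in the edgeR test. The quasi-likelihood test with Benjamini-Hochberg adjustment called 0 of 2786 genes (smallest adjusted p 0.326), with 180 higher and 122 lower in label-retaining cells at an unadjusted p under 0.05. DESeq2 called 14, 8 higher and 6 lower, of which 9 had the same sign in all 4 repeats. Nfe2l1 (adjusted p = 0.0171), Stat6 (0.0239), Sgpl1 (0.0121) and Fbxo33 (0.0148) were among its higher genes and Gm6548 (5.72e-05) and Sirt1 (0.000818) among its lower ones. limma on means of log2 rescaled values with the repeats paired called 26, all higher, among them the ribosomal protein gene Rpl36 (adjusted p = 0.00173). It also called Itgb3 (0.0105) and, among the genes above, Phf23 (0.0469). The same fit without the pairing called 0 (smallest adjusted p 0.471), as did the paired fits on the sums (0.523) and on log2 of mean rescaled values (0.0856). The level of Kidins220 was 498.2 ± 971.3 CPM (SD, n = 4), most of it from repeat 3 (1955 CPM), that of Nfe2l1 177.3 ± 193.6, of Stat6 115.1 ± 75.16 and of Phf23 76.31 ± 61.48 CPM, against 0 counts of each in the non-label-retaining sums. The exact permutation p of the detection shares of each of the 10 genes was 0.0286 (0.125 with the repeats paired), with the genes chosen on the same cells, and after adjustment over 93 named genes it was 0.222. After thinning 4 of the 10 kept it (Nfe2l1, Fbxo33, Stat6 and Phf23), Kidins220 stood at 0.429 and the other 5 at 0.143.

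The positions of the leading genes in mm10 were as follows. Kidins220 (identifier 77480) lies on chromosome 12 from 24974903 to 25063152, Nfe2l1 (18023) on chromosome 11 from 96817414 to 96829968, Stat6 (20852) on chromosome 10 from 127642955 to 127660987 and Phf23 (78246) on chromosome 11 from 69995766 to 70000011. The counts are per gene and do not separate exons, introns and UTRs.

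Genes with higher levels in the non-label-retaining sums were present in many cells of both groups. The selection favours this, since a lower label-retaining level in all 4 repeats requires counts in every non-label-retaining repeat. The filter also requires a count in at least 10 cells, and label-retaining cells detected more genes. The log2 fold changes (± SE) were -8.04 ± 3.05 for Gm6548, -8.00 ± 3.08 for Utp6, a component of the small subunit processome, -7.03 ± 2.93 for Dennd6a and -5.71 ± 2.72 for Rgs20, a regulator of G protein signalling. Inpp5f, an inositol phosphatase, stood at -4.78 ± 2.63, 2900092D14Rik at -4.41 ± 2.32, P4ha2, a collagen prolyl hydroxylase, at -4.27 ± 2.33, the dynein gene Dnah7b at -4.22 ± 2.29, the immune receptor Pilra at -4.18 ± 2.28 and Psg28 at -4.11 ± 2.31. All 10 had the same sign in 4 of 4 repeats, which the rule for named genes required. Of them 4 had an unadjusted p under 0.05, and none passed the adjusted threshold (edgeR, lowest adjusted p 0.326). Most of their levels rested on few libraries: Utp6 was at 3417 ± 6365 CPM in the non-label-retaining sums (12960 CPM in repeat 3) against 13.32 ± 8.76, and Gm6548 at 1898 ± 2547 against 7.198 ± 2.889 (SD, n = 4). Dnah7b was more even, at 33.38, 342.4, 386.9 and 355.8 CPM in the non-label-retaining sums. The low TMM factors of non-label-retaining repeats 3 and 4 (0.29 and 0.22, the other sums 1.44 to 2.04) raise CPM there and add to these contrasts. By cells, 8 of the 10 were detected in a larger share of label-retaining cells, and 0 of the 10 after thinning. Gm6548 overlaps Eif2ak2 on chromosome 17, with the same start (78850504), and Dnah7b and Psg28 belong to families of near copies, so their counts are uncertain.

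The balance of directions moved with the scaling, the filter and the repeats used. The median log2 fold change of all tested genes was 1.15 with TMM, 1.78 with total counts (230 higher and 43 lower at an unadjusted p under 0.05), 0.09 after quantile normalization (46 and 40) and 1.88 with each cell rescaled to the same total (291 and 2). With the repeat as a block the numbers were 212 and 9. The lower genes outnumbered the higher ones with the stricter filter (56 higher and 92 lower), with means weighted by cells (136 and 167), without repeat 4 (82 and 100) and without non-label-retaining repeat 2 (140 and 145). Leaving out repeats 1, 3 or 4, label-retaining repeat 4, or non-label-retaining repeats 1 or 4 moved the higher count by over 1.5 times, to between 82 and 462. Leaving out repeats 1, 2 or 3 or label-retaining repeats 1, 2 or 3 moved the lower count, to between 55 and 73.

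Members of most of the fixed lists were seen in more of the label-retaining cells, as were genes in general. All shares of members given here are over the members with a count in any cell, not over the whole list. A label-retaining cell held 28.2% ± 6.53 of all genes with any count and a non-label-retaining cell 16.0% ± 4.06, a ratio of 1.76 (SD, n = 4). Of 32 lists of both kinds with at least 3 detected members, 21 had a higher share in all 4 repeats. Among the 32, 8 had an exact permutation p under 0.05 (0.0286 each), and none passed adjustment (smallest adjusted p 0.102). After thinning 1 of the 8 remained, the Notch pathway. With the repeats paired no list can fall below p = 0.125, and each of the 8 stood there. Detection and level often differed in direction: of 65 named list members with a test of level, 62 were detected in a larger share of label-retaining cells, 24 of these had a log2 fold change under 0, and 55 of the 65 had the larger share after thinning.

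**Figure D2:**
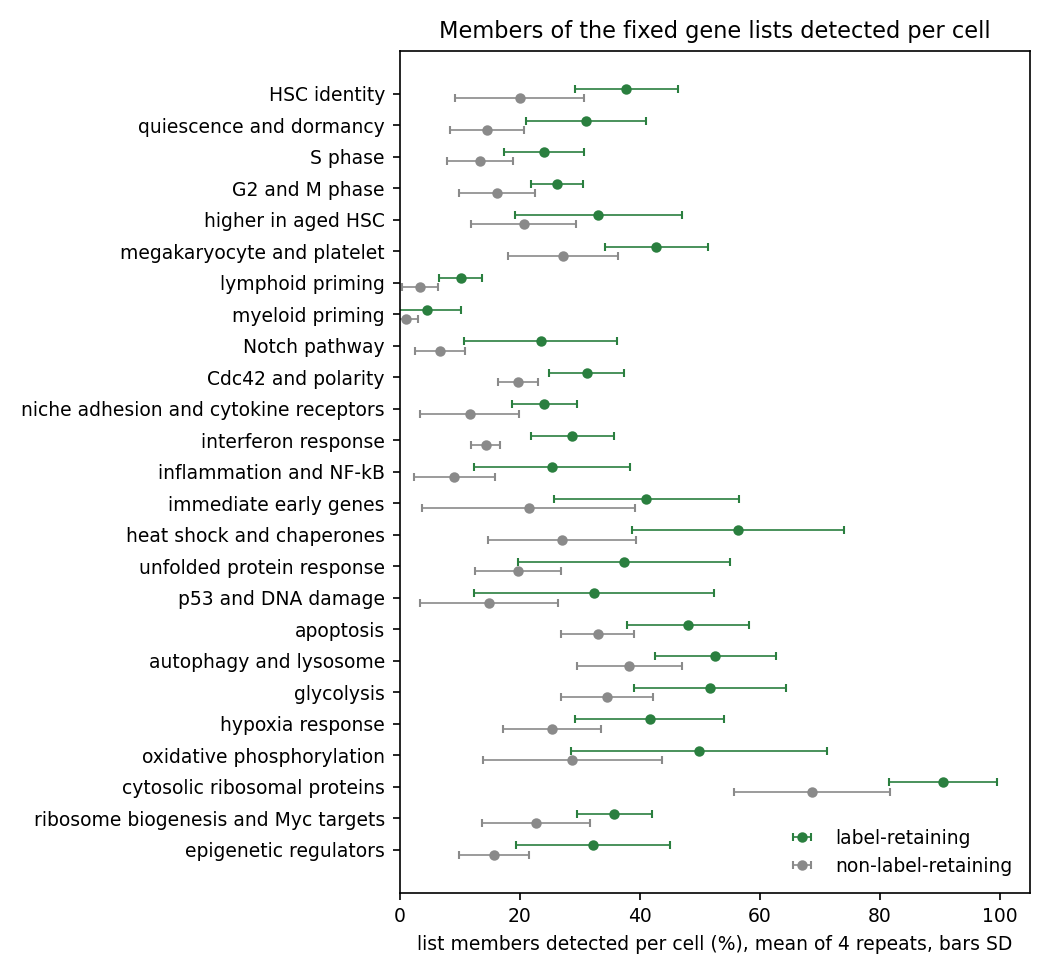
Share of the members of each fixed list that a cell detected, among members with a count in any cell (horizontal axis, percent). Points are means of the 4 repeats, bars SD. Green is label-retaining, grey non-label-retaining. For the Notch pathway the means are 23.5% and 6.70%, and for cytosolic ribosomal proteins 90.5% and 68.8%.

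The Notch pathway, through which neighbouring cells signal by contact, had the largest ratio among the lists at p = 0.0286 except the monocyte markers. Label-retaining cells detected 23.5% ± 12.8 of its 12 detected members and non-label-retaining cells 6.70% ± 4.19, a ratio of 3.51 (SD, n = 4, exact permutation p = 0.0286, higher in 4 of 4 repeats). After thinning the shares were 11.1% and 2.31% (exact permutation p = 0.0286). The list took 0.127% ± 0.109 of the counts in label-retaining and 0.0097% ± 0.00931 in non-label-retaining cells (exact permutation p = 0.0286, adjusted over 32 lists 0.458). Label-retaining repeat 3 held 0.282%, and with a repeat left out the difference ran from 0.0632 to 0.150 points. In members detected label-retaining repeat 1 stood apart (42.6%, the others 15.7 to 19.2%). Without the cells that detected under 686 genes the difference in share of counts was 0.0561 points (exact permutation p = 0.114). Psen2, the catalytic part of gamma-secretase, was detected in 10 and 0 cells and was the only member past 0.05 when adjusted over the list alone (0.0467), with 0 past over all genes. Its partner Psenen was found in 14 and 4 cells. The log2 fold change of Psenen was -3.5, through non-label-retaining repeat 4 (1616 CPM), with higher levels in label-retaining cells in 3 of 4 repeats. The ubiquitin ligase gene Dtx3 was found in 9 and 2 cells, and the ligand gene Jag2 in 2 and 0. The camera test of the 6 tested members gave an adjusted p of 0.767.

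Megakaryocyte and platelet genes, which mark a platelet-biased state of stem cells, took 0.716% ± 0.105 of the counts in label-retaining and 0.183% ± 0.143 in non-label-retaining cells (SD, n = 4, exact permutation p = 0.0286, adjusted 0.458, higher in 4 of 4 repeats). Of the 13 detected members, 42.8% ± 8.56 were seen per label-retaining and 27.2% ± 9.17 per non-label-retaining cell (exact permutation p = 0.0286), and 25.8% and 14.5% after thinning (exact permutation p = 0.143). The ratio of 1.57 lay below the 1.76 of all genes, so the difference in members detected is not particular to this list. Without the cells under 10000 counts the difference in members was 11.4 points (exact permutation p = 0.286). Itgb3, the beta subunit of the platelet fibrinogen receptor, was detected in 30 of 37 and 9 of 28 cells, and in 22 and 3 after thinning (exact permutation p = 0.0286 for both, 0.125 for the first with the repeats paired). Its partner Itga2b was found in 11 and 2 cells, Vwf, the platelet adhesion factor, in 16 and 8, and Selp in 1 and 2. Itgb3, Vwf and Clec1a (17 and 5 cells) had the smallest p on the list of genes known to be higher in aged stem cells, of which 33.1% ± 13.9 and 20.7% ± 8.76 of members were detected (exact permutation p = 0.2). Their levels went different ways, with log2 fold changes of 5.01 for Itgb3, -4.05 for Vwf and -4.46 for Clec1a. The negative values came from non-label-retaining repeat 4 alone (2438 and 8253 CPM), and the median of the aged list turned from -2.98 to 3.17 without repeat 4 and to 3.05 with the repeat as a block. Camera gave adjusted p values of 0.767 and 0.996 for these 2 lists.

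**Figure D3:**
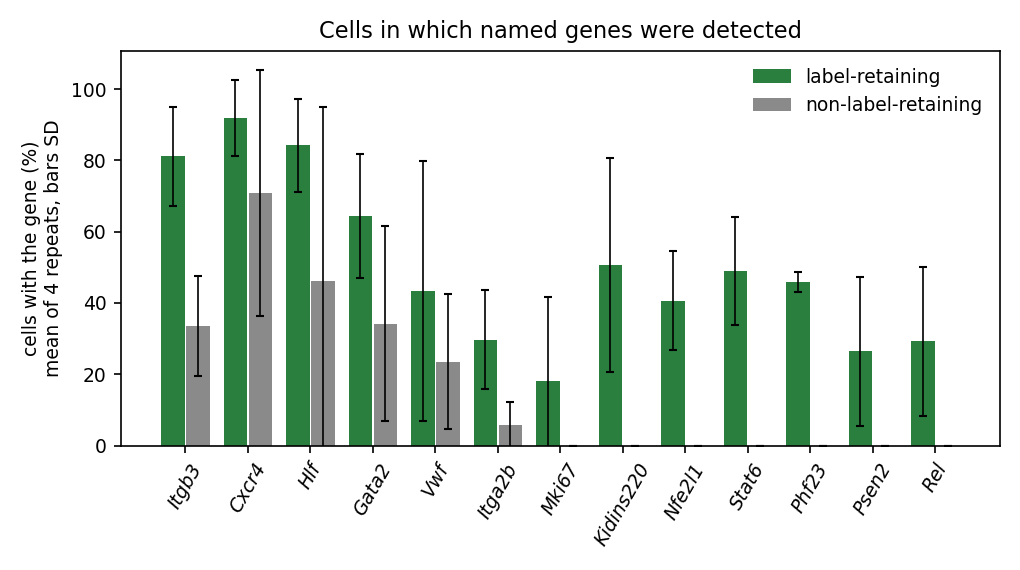
Share of cells in which 13 named genes had a count above 0 (vertical axis, percent; bars are means of the 4 repeats, error bars SD; n = 4). Green is label-retaining, grey non-label-retaining. Itgb3 stands at 81.1% and 33.5%, Phf23 at 45.8% and 0%.

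Most stem cell identity genes with a count were detected in both groups. Gcnt2 (7 of 37), Hoxa9 (5) and Hoxb5 (2) had counts in label-retaining cells alone. Hlf, a transcription factor of long-term stem cells, was found in 31 of 37 label-retaining and 12 of 28 non-label-retaining cells, Gata2 in 24 and 10, and Ifitm3 in 17 and 6. The list stood at 37.8% ± 8.52 and 20.0% ± 10.8 of its 11 members with a count, out of 33 (exact permutation p = 0.0857). Slamf1, the gene of CD150 by which the cells were sorted, and Cd48 and Flt3, by whose absence they were sorted, were seen in 0 of 37 and 0 of 28 cells (shares of cells with a read of up to 9.49% and 12.3%). Since the cells were sorted as CD150 positive, these zeros do not limit the share of cells that express the genes. Among quiescence and dormancy genes (31.0% ± 10 and 14.6% ± 6.12 of members, exact permutation p = 0.0571), 2 of 5 tested members were past 0.05 when adjusted over the list alone (smallest 0.0196) and 0 over all genes. These were the antiproliferative gene Btg2, detected in 11 and 1 cells, and the deacetylase Sirt1, in 12 and 12 cells with the higher level in 2 non-label-retaining sums (8700 and 27380 CPM in repeats 1 and 3, 3.935 and 10.54 in repeats 2 and 4). They lay on opposite sides. Btg1, a relative of Btg2, was found in 30 and 11 cells, and the cell cycle inhibitor Cdkn1c in 3 and 1. The level of Btg1 went the other way (log2 fold change -5.25, lower in label-retaining cells in 3 of 4 repeats). After thinning Btg1 was detected in 43.1% and 37.8% of cells.

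Lineage priming was sparse. Lymphoid priming genes stood at 10.2% ± 3.56 and 3.39% ± 2.94 of members (exact permutation p = 0.0571), with Cd79a in 8 and 3 cells and the transcription factor Ikzf1 in 9 and 3. Cd79a is also a B cell marker, and its level lay almost wholly in label-retaining repeat 2 (1088 CPM), where B cell markers took 0.545% of the counts. Myeloid priming genes stood at 4.63% ± 5.56 and 1.04% ± 2.08 (exact permutation p = 0.429), and Mpo and Elane were seen in 0 cells. Both lists had fewer than 5 tested members and were not tested with camera.

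Genes for contact with the niche and for cell polarity were detected in larger shares in label-retaining cells, with ratios of 2.06 and 1.59 against 1.76 for all genes (adjusted p = 0.102 for both). Niche adhesion and cytokine receptors stood at 24.1% ± 5.42 and 11.7% ± 8.27 of members (exact permutation p = 0.0286), and 15.7% and 6.86% after thinning (exact permutation p = 0.143). Cxcr4, the receptor that holds stem cells in the marrow, was found in 34 of 37 and 19 of 28 cells, the endothelial adhesion gene Pecam1 in 20 and 6, and Tgfbr2 in 13 and 5. Cdc42 and polarity genes stood at 31.2% ± 6.28 and 19.7% ± 3.36 (exact permutation p = 0.0286; 14.3% and 9.16% after thinning, p = 0.314), with Wasl in 15 and 4 cells, Septin2 in 25 and 13 and Cdc42se2 in 14 and 5.

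Stress and signalling genes were likewise detected in more label-retaining cells, with ratios from 1.46 for apoptosis to 2.79 for inflammation against 1.76 for all genes. Interferon response genes stood at 28.8% ± 6.95 and 14.4% ± 2.41 of members (exact permutation p = 0.0286, and 0.571 after thinning), with Trim30a in 18 and 5 cells, Xaf1 in 22 and 10 and Eif2ak2 in 16 and 8. Apoptosis genes stood at 48.1% ± 10.2 and 33% ± 6.03 (exact permutation p = 0.0286, and 0.886 after thinning), with the caspase inhibitor Cflar in 37 and 25 cells, Casp8 in 20 and 9 and Bbc3 in 15 and 3. Hypoxia genes, of interest after a night at low oxygen, stood at 41.7% ± 12.4 and 25.4% ± 8.20 (exact permutation p = 0.0286, and 0.314 after thinning), with P4ha2 in 23 and 10 cells, Kdm3a in 11 and 4 and Higd1a in 14 and 4. Inflammation and NF-kB genes stood at 25.4% ± 13.0 and 9.13% ± 6.78 (exact permutation p = 0.0571), with Rel in 11 and 0 cells, Ccl4 in 17 and 8 and Ccl3 in 12 and 3. Immediate early genes stood at 41.1% ± 15.4 and 21.5% ± 17.8 (exact permutation p = 0.171), with Ppp1r15a in 25 and 7 cells and Zfp36 in 19 and 10. Heat shock genes stood at 56.4% ± 17.6 and 27.1% ± 12.3 (exact permutation p = 0.0571), with Bag3 in 13 and 2, Cct4 in 25 and 12 and Hspd1 in 14 and 4 cells. The log2 fold changes of Cct4 and Hspd1 were negative (-4.45 and -6.17), each through a single non-label-retaining sum (30500 CPM in repeat 2 and 7886 CPM in repeat 4), and after thinning Hspd1 was detected in 13.9% and 18.6% of cells. Unfolded protein response genes stood at 37.4% ± 17.6 and 19.7% ± 7.20 (exact permutation p = 0.0571), with Dnajb9 in 20 and 5, Ddit3 in 24 and 14 and Asns in 17 and 11. For p53 and DNA damage the shares were 32.4% ± 20.0 and 14.9% ± 11.5 (exact permutation p = 0.171), with Plk2 in 10 and 3 cells.

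Metabolic and housekeeping lists also had more members per label-retaining cell, with ratios from 1.37 for autophagy and lysosome to 2.05 for epigenetic regulators against 1.76 for all genes. Glycolysis stood at 51.7% ± 12.7 and 34.6% ± 7.66 (exact permutation p = 0.0857), with the neuronal-type enolase gene Eno2 in 13 and 5 cells, the glucose transporter gene Slc2a3 in 31 and 21 and Ldhb in 14 and 6. Oxidative phosphorylation stood at 49.9% ± 21.4 and 28.8% ± 14.9 (exact permutation p = 0.229), with Ndufs6 in 18 and 3, Uqcrq in 16 and 7 and Ndufc2 in 8 and 6 cells. Autophagy and lysosome genes stood at 52.6% ± 10.1 and 38.3% ± 8.81 (exact permutation p = 0.0571), with the proton pump gene Atp6v1h in 29 and 10, Nbr1 in 22 and 9 and Atg12 in 16 and 3 cells. The log2 fold changes of Atp6v1h and Nbr1 were negative (-6.52 and -4.77), mainly through non-label-retaining repeat 3 (42270 and 7129 CPM), while Atp6v1h was higher in label-retaining cells in 3 of 4 repeats. After thinning their shares of cells were 22.2% and 20.2%, and 21.4% and 19.6%. Ribosome biogenesis and Myc targets stood at 35.8% ± 6.28 and 22.7% ± 8.99 (exact permutation p = 0.0571), with Npm1 in 35 and 22, Fbl in 13 and 2 and Pes1 in 9 and 4 cells. Epigenetic regulators stood at 32.2% ± 12.8 and 15.8% ± 5.81 (exact permutation p = 0.0571), with the co-regulator Cited2, a regulator of stem cell maintenance, in 26 and 5 cells, Ezh1 in 15 and 3 and Tet3 in 7 and 4. The mitochondrial genome is not analysed here.

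Cytosolic ribosomal proteins were the only list past the camera threshold, and their direction depended on how cells were scaled and combined. In the sums the 41 tested members had a median log2 fold change of -1.62, with 35 negative and 6 positive (camera, limma, adjusted p = 0.0081 over 21 lists). The call was lost with an estimated correlation (adjusted p = 0.993) and with the repeat as a block (adjusted p = 0.0551), and random lists matched on expression had a median of -1.90 with the list at percentile 76. It was also lost without repeat 3 (adjusted p = 0.343), repeat 4 (0.255), label-retaining repeat 1 (0.389), and non-label-retaining repeats 3 (0.807) or 4 (0.205). On means of log2 rescaled values per cell the list lay on the other side (median log2 fold change 2.98, adjusted p = 7.49e-15), as after quantile normalization (0.98, adjusted p = 0.00193). On log2 of the mean rescaled value, which also weighs cells equally, camera gave no call (adjusted p = 0.749). Its direction there was still down, which is relative to the other tested genes. Each label-retaining cell detected 90.5% ± 9.02 of the members and each non-label-retaining cell 68.8% ± 13.0 (SD, n = 4, exact permutation p = 0.0857), while their share of counts was 8.44% ± 2.03 and 10.1% ± 2.77 (exact permutation p = 0.4). Rpl23a was found in 34 and 23 cells, Rpl38 in 32 and 21 and Rplp2 in 32 and 21, and reads of such genes can be shared with their many pseudogenes. For the other 20 tested lists the camera adjusted p lay between 0.594 and 0.996, and for quiescence and dormancy, S phase, interferon response, apoptosis, and autophagy and lysosome the test pointed down although the median log2 fold change was above 0.

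Transcripts of other blood and marrow cells were present in both groups, unevenly between repeats. Erythroid markers, chiefly haemoglobin genes, took 2.59% ± 4.53 of the counts of label-retaining and 1.30% ± 1.27 of non-label-retaining cells (SD, n = 4, exact permutation p = 0.971), with 9.37% in label-retaining repeat 3 (Hba-a1 4.61%, Hbb-bs 3.41%) and 3.18% in non-label-retaining repeat 4. Hba-a1 was detected in 36 of 37 and 24 of 28 cells. The shares of erythroid members were 38.5% ± 6.46 and 37.2% ± 8.43 (exact permutation p = 0.886). B cell markers took 0.137% ± 0.272 and 0.0797% ± 0.159 (exact permutation p = 0.543), nearly all in repeat 2 of both groups, where the antigen presentation gene Cd74 took 0.355% and 0.318%, and their members stood at 13.7% ± 15.2 and 10.4% ± 9.99 (exact permutation p = 0.714). Monocyte and macrophage markers stood at 21.7% ± 4.67 and 5.31% ± 5.44 of 4 detected members (exact permutation p = 0.0286, and 0.4 after thinning), with 0.00469% and 0.00322% of the counts. Endothelial markers stood at 26.6% ± 17.6 and 12.5% ± 14.4 of members (exact permutation p = 0.229), dendritic cell markers at 29.2% ± 13.7 and 20.4% ± 10.6 (0.429), mesenchymal stroma markers at 13.5% ± 6.04 and 11.0% ± 5.57 (0.6) and neutrophil markers at 2.78% ± 3.55 and 1.04% ± 2.08 (0.714). For T and NK cells and for megakaryocyte progenitors 1 marker of each was detected in any cell, and for mast cells and basophils 0. None of the 10 lists had enough tested members for camera, and with no filter the erythroid list alone did (adjusted p = 0.356).

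Similarity between cells of a group did not differ beyond the spread between repeats. The mean Spearman correlation between cells of a repeat was 0.377 ± 0.0231 in label-retaining and 0.338 ± 0.0473 in non-label-retaining cells (SD, n = 4, exact permutation p = 0.2, higher in 4 of 4 repeats). Paired sign flips gave p = 0.125, the smallest they can give, and the stricter gene filter a difference of 0.0432 (exact permutation p = 0.0571). The difference of 0.0384 turned to -0.0163 without cells that detected under 686 genes and to -0.0293 after thinning (exact permutation p = 0.771 and 0.314).

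Cells with 10 or more counts of the chosen cycling genes were a minority in both groups. Of the 8 chosen genes 5 are in the table, and 7 of 37 label-retaining cells (18.9%, exact 95% interval 7.96 to 35.2%) and 2 of 28 non-label-retaining cells (7.14%, 0.877 to 23.5%) had 10 or more counts of any. The shares per repeat were 18.6% ± 15.8 and 8.75% ± 11.8 (SD, n = 4, exact permutation p = 0.314), a difference within the spread between repeats. Mki67, the proliferation marker, was detected in 7 and 0 cells, Top2a in 3 and 0, Birc5 in 17 and 11 and Cdk1 in 1 and 0. S phase genes stood at 24.1% ± 6.64 and 13.4% ± 5.50 of members (exact permutation p = 0.0571), with the replication helicase genes Mcm3 in 14 and 3 cells and Mcm7 in 13 and 1, and Ubr7 in 9 and 2. G2 and M phase genes stood at 26.2% ± 4.35 and 16.2% ± 6.34 (exact permutation p = 0.0571). Cks2 was found in 11 and 1, Lbr in 19 and 8 and Hmmr in 10 and 8 cells. After thinning the S phase shares were 10.1% and 5.69% (exact permutation p = 0.171). Those of G2 and M phase were then nearly equal, at 7.33% and 7.15%.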

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

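These values stood apart from the others of their group by Dixon's test of the largest gap, which was planned, while the list shares it was applied to were chosen after the data were examined. Of 129 groups of 4 to 10 values, 17 held such a value, against about 6.5 by chance at 1 in 20 (0.05).

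Label-retaining cell 3 of repeat 1, with 20516069 counts, lay far above the other cells of its repeat, and so did cell 36 of repeat 4, with 514659 counts.

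Repeat 1 of the label-retaining cells stood highest in the shares of members detected of the Notch pathway (42.6%), the megakaryocyte and platelet list (55.6%) and niche adhesion and cytokine receptors (32.2%). Repeat 1 of the non-label-retaining cells stood highest for p53 and DNA damage (32.0%) and for the myeloid priming and neutrophil lists (4.17% each, the other repeats at 0), and repeat 4 lowest for apoptosis (24.0%).

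Erythroid genes took 9.37% of the counts in label-retaining repeat 3. B cell genes took 0.545% in label-retaining and 0.318% in non-label-retaining repeat 2, with 36.1% of B cell members detected in the label-retaining cells of that repeat.

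Among named genes, on the scale of log2(CPM + 1), Sgpl1 stood at 0.74 in non-label-retaining repeat 1 and Fbxo33 at 1.54 in non-label-retaining repeat 3, with the other 3 repeats of each at 0. Utp6 was low in label-retaining repeat 1 (0.51) and Dnah7b in non-label-retaining repeat 1 (5.1).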

How the results depend on the processing

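The alternatives named here as added were chosen only after the data were examined: total counts without TMM, the TMMwsp variant, edgeR without the robust fit, limma on rescaled values with another pseudocount, with the repeats paired or on means of logs, thinned sums, left-out deep, shallow or shared cells, and all alternatives of detection shares. The planned pseudocount and log-mean alternatives were run on rescaled values, since limma on the unscaled values as written compares library totals, and limma without trend was not run. EdgeR and DESeq2, planned for whole reads, were run on rounded expected counts. Of the marker lists of other cell types camera ran only without a filter and only on the erythroid list (adjusted p = 0.356), so the other settings planned for them gave no value. The cause of each change below was not tested, except that leaving out repeats leaves 3 against 3, whose smallest p is 0.1, and that pairing by sign flips cannot go below 0.125.

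The count of genes past the threshold was 0 in 31 of 33 alternatives, and 14 with DESeq2 and 26 with limma on means of log2 rescaled values with the replicate block. The number of fixed lists past it, 1, became 0 with no filter, with the replicate block, without cells that detect few genes, with total counts, with thinned sums, with limma on rescaled values (each pseudocount, and with the replicate block), with limma on unscaled values and with an estimated correlation, and lay between 0 and 1 when repeats or single sums were left out. The ribosomal list turned to higher with quantile normalization (adjusted p = 0.00193), with limma on means of log2 rescaled values (7.49e-15, and 1.12e-14 with the replicate block) and on unscaled values (0.352). On the same 3 log-scale fits, Rgs20 stood at a log2 fold change of 0.64, 0.64 and 0.02, Pilra at 0.04, 0.04 and 0.33, P4ha2 at 0.25 and 0.25 on the means of logs, and Inpp5f at 0.17 on unscaled values. With a repeat left out the range was -7.22 to -0.22 for Rgs20, -6.06 to -1.81 for P4ha2, -4.61 to -3.03 for Pilra and -4.82 to -3.68 for Inpp5f. In 669 of 684 settings the 20 genes kept their direction and side, though not their size, in 9 they turned, and in 6 they passed the threshold. These genes were chosen for the same sign in all 4 repeats, and none was past the threshold in the main test. The count is therefore no independent measure of stability.

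The difference in genes per cell (834) was 292.3 after thinning (exact permutation p = 0.229), 729.6 without cells that detect few genes and 682.8 without cells under 10000 counts (0.0571 each), 678.4 to 989.5 with a repeat left out, and stayed 834 with the replicate block (0.125). Similarity between cells turned to -0.01627 without cells that detect few genes and -0.02931 after thinning. The cycling share kept its direction and stayed short of the threshold in 9 of 9 alternatives (differences 3.148 to 17.78 points).

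For members detected per cell, in percentage points, the megakaryocyte and platelet list stood at 15.6 with the replicate block, 11.3 thinned, 11.9 without cells that detect few genes, 11.4 without cells under 10000 counts and 14.1 to 19.5 with a repeat left out. Its share of counts differed by 0.533 with the block and 0.477 to 0.621 with a repeat left out. The Notch pathway stood at 16.8 with the block and 12.4 to 19.0 with a repeat left out, its share of counts at 0.118 with the block, 0.0561 without cells that detect few genes and 0.0632 to 0.150 with a repeat left out. Erythroid members turned to -7.90 thinned, -2.41 without cells that detect few genes and -1.96 without cells under 10000 counts, and mesenchymal stroma members to -1.40 thinned. With a repeat left out erythroid members ranged from -3.47 to 5.25, the erythroid share of counts from -1.10 to 2.61 and neutrophil members from -0.154 to 3.70.

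Of 720 settings for the detection of 90 named genes with a count, 611 kept direction and side. In 70 a gene no longer reached p under 0.05, in 5 it newly reached it, and in 34 it turned. Thinning turned the differences of P4ha2 (-1.97), Tgfbr2 (-2.94), Eif2ak2 (-9.92), Xaf1 (-1.14), Hspd1 (-4.71), Asns (-2.48), Cflar (-3.69), Slc2a3 (-0.407) and Ndufc2 (10.8), and among the genes with higher levels in non-label-retaining sums also Gm6548 (-19.7), Utp6 (-15.6), Rgs20 (-4.24), 2900092D14Rik (-10.6), Dnah7b (-16.7), Pilra (-1.81) and Inpp5f (-34.9). Leaving out cells that detect few genes turned Zfp36 (-2.62), Slc2a3 (-3.77), Utp6 (-4.72) and Inpp5f (-5.56), and leaving out cells under 10000 counts turned Slc2a3 (-2.10), Rpl23a (-1.53), Utp6 (-10.5) and Inpp5f (-5.56). With a repeat left out the range was -14.7 to 0.833 for Hmmr, -0.0926 to 17.9 for Eif2ak2, -11.5 to 13.8 for Slc2a3, -1.30 to 19.1 for Ldhb, -5.00 to 13.9 for Tet3, -0.463 to 7.41 for Cdkn1c, -8.33 to 3.70 for Selp, -6.67 to 9.44 for Utp6 and -16.7 to 5.19 for Dennd6a. By paired sign flips every detection share at an exact p of 0.0286, of 12 genes and of 8 lists, stood at 0.125, the smallest possible. The shares of counts of the megakaryocyte and platelet list and of the Notch pathway, at an exact permutation p of 0.0286, also stood at 0.125 by sign flips. No other call of this section changed with the replicate block. Depth limits the genes with few counts most, and the table covers part of each library only.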

Other observations

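All tests in this part were chosen only after the result was seen, except the counts over other splits of the samples.

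The 4 genes of the Y chromosome examined here reached 10 counts in label-retaining cells alone. Ddx3y, Eif2s3y, Kdm5d and Uty, which male cells use throughout the body, reached 10 counts in 18 of 37 label-retaining cells and 0 of 28 non-label-retaining cells. By repeat the label-retaining cells at 10 counts or more numbered 6 of 9, 7 of 9, 3 of 10 and 2 of 9, against 0 in each non-label-retaining repeat (means 49.2% ± 27.2 and 0%, SD, n = 4, exact permutation p = 0.0286, and 0.0571 for any count after thinning). Ddx3y reached 5212 counts in a label-retaining cell and 6 in a non-label-retaining cell, Eif2s3y 3689 and 2, Kdm5d 3076 and 5, and Uty 1135 and 0. Any count of the 4 genes was seen in 28 and 12 cells.

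Lower depth in the non-label-retaining cells could not be settled as a cause. Of 10000 random sets of other genes matched on label-retaining cells at 10 counts, 0.58% reached as few non-label-retaining cells as Ddx3y, Eif2s3y and Kdm5d. The median of the sets was 4 cells. The sets were matched on that number of cells and not by repeat. Most of the label-retaining cells at 10 counts lay in repeats 1 and 2, where median depth favoured the label-retaining cells. The low share of sets therefore does not exclude depth. Animals of the other sex behind the non-label-retaining cells may account for the 0 of 28 cells at 10 counts. By itself that does not account for the counts of up to 6 seen in 12 of these cells. The labels give no sex and Xist is not analysed here. A loss of the Y chromosome from non-label-retaining stem cells of aged males would give the same 0 and was not tested. Sex and loss of the chromosome cannot be told apart here, nor from lower depth in repeats 1 and 2. If sex differed between the groups, it would also be part of every comparison between them.

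Libraries next to each other in index order were alike. Within a repeat and group, neighbours correlated with r = 0.485 (55 pairs) and pairs 2 or more positions apart with 0.333 (192 pairs), a difference of 0.152 (permutation p = 1e-05, the smallest 100000 permutations can give). This argues against a state shared by the cells of a repeat and group as the whole cause, since such a state has no order. Reads given to a wrong library through a shared i5 index would link all pairs with that index alike, but neighbours exceeded the other pairs of the same i5 index by 0.158. Material or reads carried over between libraries handled side by side remains a candidate explanation, and neighbours sorted or made in the same batch of handling stay open.

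The closest pairs were label-retaining cells 20 and 21 (r = 0.973), 21 and 22 (0.935) and 20 and 22 (0.934) of repeat 3. In repeat 1, label-retaining cell 3 (20516069 counts) and non-label-retaining cell 3 (340279 counts) had r = 0.911 although they lie at index positions 7 and 17, and the second held a median of 0.0158 of the counts of the first over 1468 shared genes (quartiles 0.0132 and 0.0186). Without both cells 306 genes were higher and 133 lower at an unadjusted p under 0.05, and 0 passed adjustment.

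For the larger number of genes in label-retaining cells, in repeats 3 and 4, where non-label-retaining cells had at least the same median depth, the thinned difference was 520 genes, beyond the spread between repeats, which argues against sequencing depth there, while in repeats 1 and 2 it was 64.3, within that spread. Over all repeats failed libraries cannot be told apart from a difference between the cells: without the cells under 10000 counts the difference kept most of its size (682.8 of 834) but not its call (exact permutation p = 0.0571). The 520 genes of repeats 3 and 4 already leave those cells out, so cells under 10000 counts do not account for that part. Libraries that failed in another way, with many counts from few genes, pass this minimum and were not tested. Index order cannot be told apart either: inside a repeat and group genes per cell had a mean rho of -0.0509 with position (permutation p = 0.722), and the groups occupy separate positions. The RNA content of label-retaining cells and the yield of each library stay open and were not tested.

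For the comparison of genes past adjustment, 35 of the 35 splits of the 8 sums gave at least the 0 genes of the real split, as they must, so this count carries no information (highest other 2). At an unadjusted p under 0.05 the real split gave 302 genes, 15 of 35 splits gave as many and the highest other gave 593, so chance cannot be excluded. The 14 splits with more genes each leave at least 1 pair of repeats together, and in 13 of them this is label-retaining with non-label-retaining repeat 1, the repeat with the 2 cells that share a profile. Among the 8 splits that part all 4 pairs the real one gave the most (highest other 241), too few splits for a share under 0.05. For the fixed lists 25 of 35 splits gave at least the 1 list of the real split, and the highest other gave 3.

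Between repeats, Malat1, a nuclear RNA, took a mean of 2.18% of the counts in repeats 1 and 2 and 7.62% in repeats 3 and 4, in both groups alike.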
